A study of Mus musculus with 8 samples.

How the data were processed

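Granulosa cells of ovarian follicles were cut from mouse ovary cryosections by laser microdissection, and their polyadenylated RNA was reverse transcribed, amplified with the Smart-seq2 method and made into libraries with the Tn5 transposase, per the labels' protocols. The method does not mark the strand of a read, so overlapping and antisense genes cannot be told apart. There were 8 libraries, 2 of the conditional knockout (cKO) and 6 without Cre (WT). The genotype label calls the cKO group a knockdown. The description of all 8 samples gives a library name that begins with cKO, also for the 6 samples that the title and the genotype label call WT. Groups were taken from the titles, and the doubt this leaves about the WT labels applies to each comparison. How follicles were chosen and how many animals were used is not given in the sources used here.

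The authors deposited 1 quantification table per library with estimated counts of reads, TPM values and transcript lengths per row. The submitters' processing notes name HISAT2, Salmon and the mm10 genome, without versions, and the annotation is not given in the sources used here. Each table held 36635 rows, of which 35087 carry a gene name and 1548 a transcript identifier only. The latter name no gene, took from 0.435% to 0.739% of reads, and were left out of library sizes and tests. Of the named rows, 34130 matched the names of the reference annotation (GENCODE M21, on GRCm38, the assembly that mm10 denotes) and 957 did not. Coordinates are from that annotation.

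The deposited estimated counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 15102 genes. Library sizes were scaled by TMM, and groups were compared with edgeR 4.0.16 (glmQLFit and glmQLFTest, group as the only term) in R 4.3.3 with Benjamini-Hochberg adjustment and a threshold of 0.05. Normalised read counts are CPM after TMM. A log2 fold change is cKO against WT, and its standard error was derived from the F statistic. The common biological coefficient of variation was 0.699. The median log2 fold change over all genes was -0.08 with TMM and 0.05 with DESeq2's size factors, so directions of that size depend on the scaling.

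In total 29 gene lists were fixed before the data were examined and tested with camera from limma 3.58.1 on all tested genes, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. For each list, members were also adjusted over the list alone, which gave 14 passing members in 7 lists. Shares of reads on marker lists of other cell types and on the mitochondrial genome were compared by an exact two-sided permutation test over the 28 splits of 8 libraries into 2 and 6, which cannot give a p below 0.036. A few list genes (3) were not among the rows.

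Named genes followed a rule fixed in advance: Hif1a, Bcl2l1, Bcl2l11, Foxo1 and Foxl2 always; as no gene passed the adjusted threshold, the 5 genes with the smallest p in each direction among those with a gene name other than a Gm or Rik number and no overlap between groups; and from each list with no member past the threshold the 2 members with the smallest p. Genes named outside the rule are said to have been chosen after their values were seen.

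Depth ranged from 651426 to 4719293 reads on named genes per library. A gene with no read could have had up to 3 reads, which is from 0.636 to 4.61 CPM per library. Reads were amplified without molecular identifiers, so such limits cover counting error only. No pair of libraries agreed within sampling noise: over the 28 pairs the chi-square statistic per degree of freedom lay between 13.0 and 99.5.

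The fit was tested on simulated counts drawn from the means, dispersions and library sizes of the 15102 genes, with 200 genes changed. For the comparison of cKO with WT, 17% of the genes changed 4-fold and 59% of those changed 16-fold were called, with 2 false calls. In an unchanged simulation 1 gene and 0 lists were called. The simulation draws genes independently, so it does not test lists of correlated genes.

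Alternatives planned before the data were examined were DESeq2's size factors, no TMM factor, no filter, a filter of 10 reads in 6 libraries, DESeq2 1.42.0, limma-voom with quality weights, limma on log2(TPM + 1) of the deposited TPM, robust dispersion, an effective length offset, the replicate number as a block, the number of detected genes (5 reads) as a covariate, removal of mitochondrial genome genes, and leaving out each library. Alternatives added after seeing the data were the libraries numbered 1 and 2 alone (picked once Gm47283 and then granulosa genes, Amh, Inha, Inhba, Hsd3b1 and Cyp19a1, had set them apart from WT replicates 3 to 6, so a list holding these genes shrinks there by that choice), those libraries with an estimated correlation for the lists, removal of 5 further abundant rows (Lars2, Gm20594, Gm47283, Gm10925 and Gm29216), thinning every library to 651426 reads, and, beside the random matched lists, each library left out and the gap to matched genes per library. Similarity of those rows to mitochondrial transcripts was measured with blastn 2.17.0. Random matched lists and permutations used Python 3.11.15 with numpy 2.4.6.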

Results

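RNA of ovarian granulosa cells, the somatic cells that surround the oocyte in a follicle, was sequenced after laser microdissection from mouse ovary sections. Mice of both groups carried Hif1a alleles flanked by loxP sites, which Cre recombinase can excise. The cKO group (n = 2 libraries) also carried Foxl2-CreERT2, a tamoxifen-inducible Cre expressed from the granulosa cell gene Foxl2, and the WT group (n = 6 libraries) did not. Tamoxifen at 100 mg/kg was given daily for 5 days from 3 weeks of age, and ovaries were taken 7 days after the last dose. The 2 cKO libraries held 2054584 and 651426 reads on named genes, and the 6 WT libraries held 1594803, 4305155, 2330139, 4719293, 4617477 and 4615477. The library names in the descriptions begin with cKO for all 8 samples, against the titles and genotype labels, which were followed. The labels tie no library to an animal or a follicle stage. Some libraries may share an animal, in which case the p-values over libraries are too small, and they measure the spread between these libraries only.

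The first question was whether Hif1a, which encodes the oxygen-regulated subunit of the transcription factor HIF1, was lower in the libraries labelled cKO. Hif1a (chromosome 12, 73901375 to 73947530, plus strand) had a normalised read count of 22.3 and 13.7 CPM in cKO replicates 1 and 2, below each of the WT libraries at 37.9, 35.5, 69.8, 96.5, 106.2 and 49.5 CPM in replicates 1 to 6. The group means were 17.99 ± 6.13 CPM (SD, n = 2) in cKO and 65.9 ± 30.2 CPM (SD, n = 6) in WT, a log2 fold change of -1.84 ± 0.58 (SE), with an adjusted p = 0.369 over all genes in edgeR's quasi-likelihood test. Reads outside the excised part also count toward the gene, so a remaining level does not contradict a label.

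The series title names 3 further genes. Bcl2l1 (chromosome 2, 152780668 to 152831728, minus strand) encodes the anti-apoptotic protein Bcl-XL. It had 39.8 ± 17.6 CPM in cKO (SD, n = 2) and 99.3 ± 27.3 CPM in WT (SD, n = 6), a log2 fold change of -1.30 ± 0.49 (SE, edgeR adjusted p = 0.372), and WT replicate 1 lay at 47.3 CPM, inside the cKO range of 27.3 to 52.3 CPM. Bcl2l11 (chromosome 2, 128126038 to 128162547, plus strand) encodes the pro-apoptotic protein Bim. It had 10.5 ± 10.99 CPM in cKO and 21.4 ± 3.30 CPM in WT, a log2 fold change of -0.94 ± 0.66 (SE, edgeR adjusted p = 0.563). This value rested on 1 library, as cKO replicates 1 and 2 had 18.3 and 2.73 CPM. It was -0.29 without cKO replicate 2 and -3.01 without cKO replicate 1. The 2.73 CPM lay below the limit of 3 reads in that library, 4.61 CPM, so the size of -3.01 is uncertain. Foxo1 (chromosome 3, 52268336 to 52353221, plus strand), a transcription factor gene abundant in granulosa cells, had 607 ± 256 CPM in cKO and 1633 ± 719 CPM in WT, a log2 fold change of -1.43 ± 0.68 (SE, edgeR adjusted p = 0.411). Foxl2 (chromosome 9, 98955288 to 98958543, plus strand), the gene whose promoter drove Cre, had a log2 fold change of -0.68 ± 0.55 (SE, edgeR adjusted p = 0.616). It was -1.02 without cKO replicate 1 and -0.30 without WT replicate 3. All of these means were lower in cKO, and none of the differences passed the adjusted threshold. The libraries numbered 1 and 2 were also compared alone, a choice made after Gm47283 and then granulosa genes, Amh and Inhba among them, were seen to set these libraries of both groups apart from WT replicates 3 to 6. Among them the log2 fold change was -0.94 for Hif1a, -0.88 for Bcl2l1, -1.02 for Bcl2l11 and -0.26 for Foxo1.

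**Figure D1:**
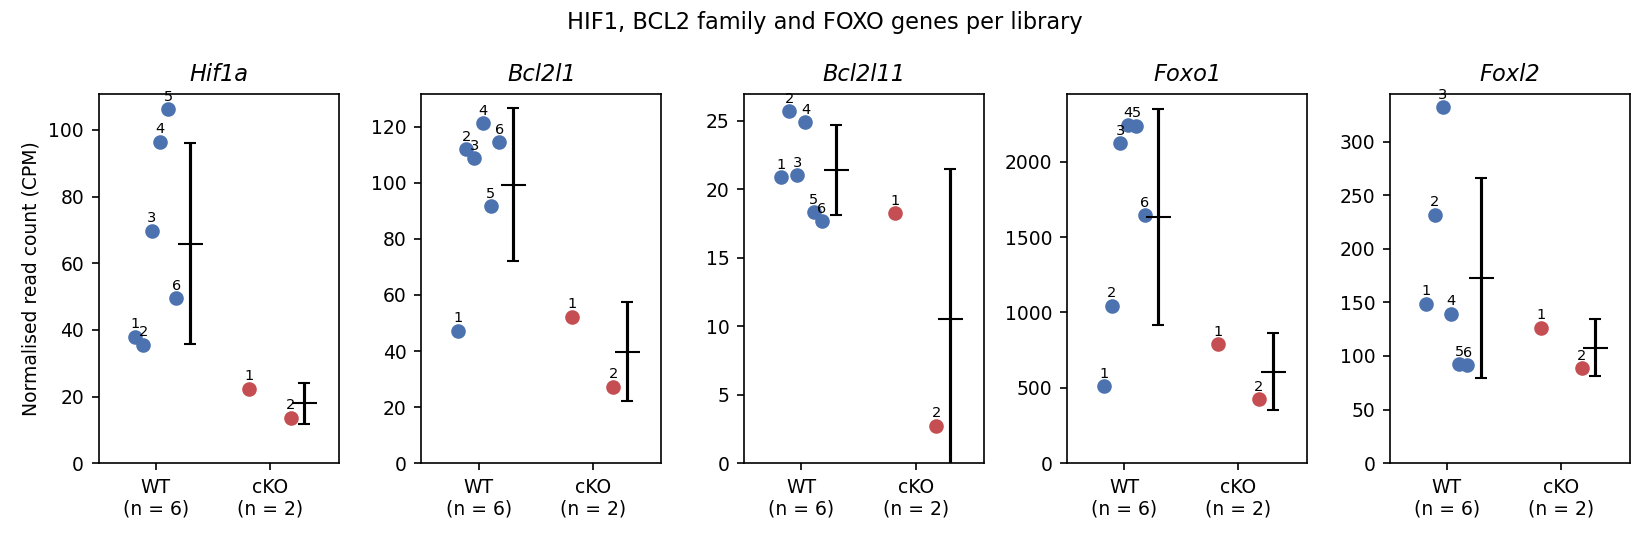
Normalised read count (CPM, vertical axis) of Hif1a, Bcl2l1, Bcl2l11, Foxo1 and Foxl2 in each WT (blue, n = 6) and cKO (red, n = 2) library; numbers beside the points are replicate numbers, and black marks are group means with SD, drawn down to 0 where the SD is larger than the mean. Both cKO libraries lie below every WT library for Hif1a, at 22.3 and 13.7 CPM.

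Across the transcriptome, the genes with the smallest p that were lower in cKO were Bckdha, a subunit gene of the branched-chain keto acid dehydrogenase, then Fam3a, Smim3, Pdlim1 and Dph3. Bckdha had 9.93 ± 2.46 CPM in cKO (SD, n = 2) and 101.7 ± 29.5 CPM in WT (SD, n = 6), a log2 fold change of -3.32 ± 0.54 (SE). The values for Fam3a, Smim3, Pdlim1 and Dph3 were -4.58 ± 0.85, -4.91 ± 0.94, -3.84 ± 0.77 and -2.42 ± 0.51. Fam3a and Smim3 rested on 4 and 6 reads in cKO, so the size of their change is uncertain. The genes with the smallest p that were higher in cKO were Myh6, a cardiac myosin heavy chain gene, with 94.6 ± 58.5 CPM in cKO and 2.46 ± 3.23 CPM in WT (log2 fold change 5.31 ± 1.05), then Cd209g (5.58 ± 1.14), Zc3h7a (1.71 ± 0.38), Sphk1, which encodes a sphingosine kinase (4.49 ± 1.04), and Inf2, which encodes a formin (2.48 ± 0.58, and 1.596 without cKO replicate 1). These 10 genes were chosen among those whose groups do not overlap, and each had an edgeR adjusted p = 0.369. Cd209g rested on 8 reads in the WT libraries together. Of 15102 genes tested, edgeR's quasi-likelihood test called 0 at an adjusted p under 0.05, while 1855 had an unadjusted p under 0.05, of which 1342 were lower and 513 higher in cKO. DESeq2 gave an adjusted p to only 6646 genes and called 253 of them, 227 lower and 26 higher, including Bckdha, Smim3, Pdlim1, Dph3 and Zc3h7a. It gave none to Fam3a, Myh6, Cd209g, Sphk1 and Inf2. The limma-voom fit with quality weights called 0. With limma-voom the balance turned, with 1458 genes higher and 1028 lower at an unadjusted p under 0.05. The unadjusted count was 865 without cKO replicate 2 and 3015 without WT replicate 1. In 1877 genes (12.4%) the 2 groups did not overlap, where chance gives 7.14% on average over splits. How widely this share varies between splits was not measured, so an excess over chance is not shown.

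Genes that HIF1 is known to induce in glycolysis were lower in cKO as a list. Of 22 members, 17 were lower and 5 higher, with a median log2 fold change of -0.67, and the list passed camera's test with a preset correlation (adjusted p = 0.011) but not with an estimated one (adjusted p = 0.524 with an estimated correlation). Tpi1 (triosephosphate isomerase) had 53.05 ± 18.996 CPM in cKO and 414 ± 252 CPM in WT, a log2 fold change of -2.95 ± 0.94 (SE, edgeR adjusted p = 0.369). Ldha (lactate dehydrogenase A) had 56.9 ± 20.7 CPM against 289 ± 181 CPM, a log2 fold change of -2.33 ± 0.75 (SE, edgeR adjusted p = 0.369). DESeq2 called 6 of the 14 members it tested, all lower, with an adjusted p = 0.0131 for Tpi1 and 0.0264 for Ldha. WT replicate 1, with 34.1 CPM of Tpi1, was below both cKO libraries. Ldha was lower in cKO with no overlap between the groups. Against the direction of the list, Pdk1, a pyruvate dehydrogenase kinase gene, was higher in cKO with no overlap (37.3 ± 2.52 against 18.6 ± 3.71 CPM, log2 fold change 1.01, unadjusted p = 0.048, edgeR adjusted p = 0.405). With the number of detected genes as a covariate, which does not overlap between the groups (at most 12847 in cKO, at least 13597 in WT), the list did not pass (median -0.76, camera adjusted p = 0.240). In the libraries numbered 1 and 2 the median of this list was -0.15, with Tpi1 at -0.90 and Ldha at -0.60, and without cKO replicate 2 the list did not pass (median -0.57); the median was -1.19 without cKO replicate 1 and -0.41 without WT replicate 3. Other HIF1 targets (30 tested) had a median of -0.40 and did not pass the list test (camera adjusted p = 0.155). Among them, Angptl4 had a log2 fold change of -1.41 ± 0.53 and Bnip3l, a mitophagy receptor gene, -1.81 ± 0.74. Bnip3l had 45.2 and 8.20 CPM in cKO replicates 1 and 2, and its value was -3.64 without the first and -1.20 without the second. Vegfa was higher in cKO with no overlap (57.9 ± 2.74 against 35.1 ± 13.8 CPM, log2 fold change 0.73, edgeR adjusted p = 0.528). It was the 1 member of its list higher with no overlap, while 3 were lower with none, Angptl4, Car9 and P4ha1. Car9 had no read in cKO. Pdk1, Vegfa, Car9 and P4ha1 were singled out after their values were seen. The median of the list was -1.14 without cKO replicate 1, -0.65 without WT replicate 1 and -0.16 without WT replicate 5. Components of the HIF pathway (11 tested) had a median of -0.40 (camera adjusted p = 0.146), which was -1.01 without cKO replicate 1 and -0.10 without WT replicate 5. In this list 2 members, Hif1a and Vhl, passed when adjusted over the list alone (adjusted p = 0.040 for each), while over all genes edgeR called 0 members, with 3 members at an unadjusted p under 0.05. DESeq2 called 0 of the 7 members to which it gave an adjusted p, and Vhl was not among these. Vhl encodes the ubiquitin ligase subunit that marks HIF1 for degradation, and it rested on 4 reads in cKO, all in cKO replicate 1 (log2 fold change -4.13). Without that library cKO had 0 reads, so the fitted -9.22 is not a measured size. The limit of 3 reads in cKO replicate 2 is 4.61 CPM, against a mean of 23.6 CPM in WT.

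The pro-apoptotic BCL2 family and caspases were also lower as a list, with 17 of 22 members lower and a median of -0.86 (camera adjusted p = 0.049, and adjusted p = 0.524 with an estimated correlation). The call was lost with detected genes as a covariate (median -0.35, camera adjusted p = 0.682), in the libraries numbered 1 and 2 (median -0.44, camera adjusted p = 0.130), and also without cKO replicate 2 (median -0.29), WT replicate 1 (-0.73) or WT replicate 3 (-0.80). Its members with the smallest p were Casp2 (log2 fold change -2.97 ± 0.99, SE) and Cycs, which encodes cytochrome c (-1.51 ± 0.62). Casp2 rested on 11 reads in cKO, with 0 in cKO replicate 2, and its value was -2.32 without cKO replicate 2. Without cKO replicate 1 no read was left in cKO, so the fitted -9.38 is not a measured size. The limit of 3 reads there is 4.61 CPM, against a mean of 26.5 CPM in WT. Anti-apoptotic BCL2 family members and inhibitors of apoptosis (10 tested, 7 lower) had a median of -0.75 and did not pass the list test (camera adjusted p = 0.163). The median was -0.49 without WT replicate 6. Next to Bcl2l1 this list named Bcl2l10, at -4.23 ± 1.81, a gene also expressed in oocytes. Bcl2l10 had 306 and 167 CPM in WT replicates 6 and 2, the libraries with the largest shares of oocyte markers. It had from 3.63 to 27.5 CPM in the other WT libraries, and 6.60 and 1.37 CPM in cKO replicates 1 and 2. FOXO factors and their targets (27 tested) had a median of -0.41 (camera adjusted p = 0.365), with Cat (catalase) at -2.10 ± 0.995, or -3.23 without cKO replicate 1. The median was -1.06 without cKO replicate 1, and -0.23, -0.26, -0.20 and -0.26 without WT replicates 3, 4, 5 and 6. The p53 targets (15 tested) had a median of -0.25 (camera adjusted p = 0.583), with Trp53inp1 at -2.46 ± 1.31 (6 reads in cKO) and Aen at -1.22 ± 0.70. Aen had 39.6 and 4.10 CPM in cKO replicates 1 and 2, and its value was -3.77 without the first and -0.51 without the second. In cKO replicate 2, Aen and Cat each had 4.10 CPM, near its limit of 3 reads (4.61 CPM). The sizes of -3.77 and -3.23 are therefore uncertain. The median of the p53 list was -0.63 without cKO replicate 1, -0.00555 without cKO replicate 2 and -0.0127 without WT replicate 2. No member of these 4 lists passed when adjusted over the list alone.

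Granulosa identity genes were lower in cKO as a list, with 21 of 28 members lower and a median of -1.24 (camera adjusted p = 0.000702, and adjusted p = 0.524 with an estimated correlation). In the same libraries stroma and endothelial markers were higher as lists with the preset correlation (medians 0.61 and 0.77) but not with an estimated one (adjusted p = 0.664 and 0.526), nor without cKO replicate 1 (medians -0.59 and 0.0454). Both marker lists passed with detected genes as a covariate (medians 3.20 and 3.37). The mitochondrial genome took 9.69% of reads in cKO and 2.77% in WT. Fshr, the receptor gene for follicle-stimulating hormone, had 8.74 ± 2.71 CPM in cKO and 77.1 ± 39.6 CPM in WT, a log2 fold change of -3.09 ± 0.67 (SE), and passed when adjusted over the list alone (adjusted p = 0.012) but not over all genes in edgeR (adjusted p = 0.369), while it did in DESeq2 (adjusted p = 0.00221). Hsd17b1, an enzyme gene of estradiol synthesis, had a log2 fold change of -3.03 ± 1.02 (SE, edgeR adjusted p = 0.369, DESeq2 adjusted p = 0.0111). DESeq2 called 6 of the 24 members it tested, all lower. The WT libraries themselves differed widely in this list. Inhba, a subunit gene of activin and inhibin, had 351 and 61.5 CPM in cKO replicates 1 and 2 and 51.7 and 93.5 CPM in WT replicates 1 and 2, but 4846, 11052, 5939 and 2250 CPM in WT replicates 3 to 6. Amh, which encodes anti-Müllerian hormone, had 610 and 224 CPM in the cKO libraries, 767 and 1126 CPM in WT replicates 1 and 2, and 2.34, 49.8, 29.2 and 176 CPM in WT replicates 3 to 6. Inhba and Amh were singled out after their values were seen. Among the libraries numbered 1 and 2 the median of the list was -0.23 and the list did not pass (camera adjusted p = 0.090), with Fshr at -2.19. Without cKO replicate 2 it did not pass either (median -0.91), nor with detected genes as a covariate (median -0.52, camera adjusted p = 0.476). Hsd17b1 was at -0.68 in the libraries numbered 1 and 2. Luteinization and progesterone synthesis genes (15 tested) had a median of -0.52 (camera adjusted p = 0.365). Hsd3b1, an enzyme gene of progesterone synthesis, was at -3.58 ± 1.38 and Lhcgr, the luteinizing hormone receptor gene, at -2.41 ± 1.15. Both values rested on WT replicates 3 to 6. Hsd3b1 had 616 and 202 CPM in cKO replicates 1 and 2, 277 and 684 CPM in WT replicates 1 and 2, and from 2026 to 12761 CPM in WT replicates 3 to 6. Lhcgr had 16.2 and 10.9 CPM in cKO, 14.3 and 2.73 CPM in WT replicates 1 and 2, and from 37.8 to 154 CPM in WT replicates 3 to 6. Hsd3b1 was at -0.14 in the libraries numbered 1 and 2, where Lhcgr turned to 0.72. Genes of cumulus expansion and ovulation (6 tested) had a median of 0.69 (camera adjusted p = 0.186), with Btc at 0.995 ± 0.95 and Vcan at 0.39 ± 0.39, or 0.24 without cKO replicate 1. The basal lamina list (12 tested, 11 higher) had a median of 0.33 (camera adjusted p = 0.103), which was -0.17 without cKO replicate 1, 0.67 without cKO replicate 2 and 0.51 without WT replicate 1 or 5. Agrn (agrin), at 1.34 ± 0.36, passed when adjusted over the list alone (adjusted p = 0.031) and was called by DESeq2 (adjusted p = 0.0264). Lamc1 was at -0.75 ± 0.50, or -1.13 without cKO replicate 1.

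**Figure D2:**
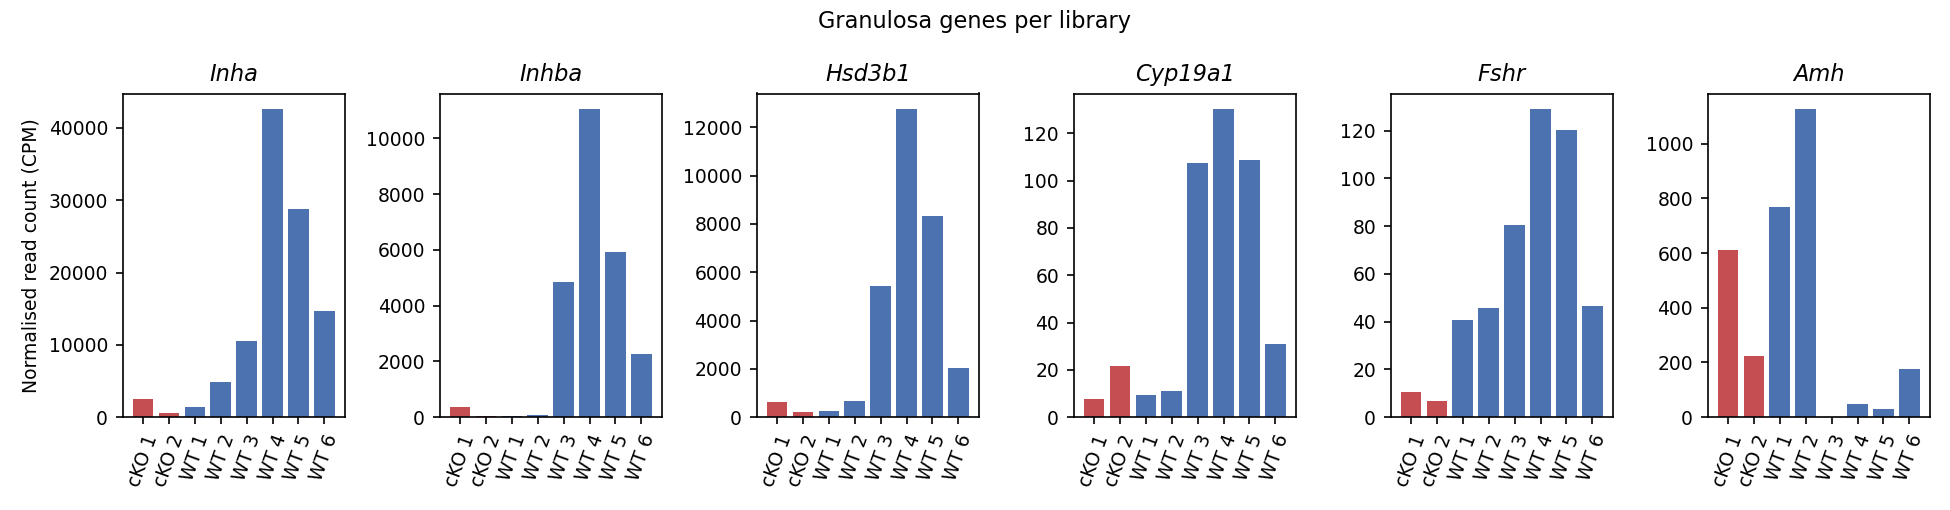
Normalised read count (CPM, vertical axes) of Inha, Inhba, Hsd3b1, Cyp19a1, Fshr and Amh in each of the 8 libraries (horizontal axis; bars, cKO red and WT blue). Inhba was at 51.7 and 93.5 CPM in WT replicates 1 and 2, near the cKO libraries, and from 2250 to 11052 CPM in WT replicates 3 to 6.

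The lists with the smallest camera p were both mitochondrial, and they lay in opposite directions. All 37 nuclear-encoded oxidative phosphorylation genes were lower in cKO, with a median of -1.27 (camera adjusted p = 7.56e-15), and all 13 mitochondrial genome genes were higher, with a median of 1.34 (camera adjusted p = 1.49e-11). With an estimated correlation the adjusted p = 0.524 for each. With the number of detected genes as a covariate, the nuclear list did not pass (median -0.38, camera adjusted p = 0.393) and the mitochondrial genome list did (median 2.05, camera adjusted p = 4.47e-10). Cox8a and Cox5a, nuclear genes for cytochrome c oxidase subunits, had log2 fold changes of -2.35 ± 0.64 and -3.70 ± 1.03 (SE), and mt-Co1 and mt-Nd5 on the mitochondrial genome had 2.24 ± 0.71 and 1.76 ± 0.53. Cox5a was at -5.63 without cKO replicate 1. It had 4.10 CPM in cKO replicate 2, near the limit of 3 reads there (4.61 CPM), so that size is uncertain. Adjusted over the list alone, 3 nuclear and 5 mitochondrial genome members passed in edgeR. Over all genes edgeR called 0 of either list, with 17 nuclear and 7 mitochondrial genome members at an unadjusted p under 0.05. DESeq2 called 7 of 37 nuclear genes, all lower, and 5 of 13 mitochondrial genome genes, all higher. Its adjusted p was 0.00355 for Cox8a, 0.00267 for Cox5a, 0.00541 for mt-Co1 and 0.00399 for mt-Nd5. Ribosomal protein genes were lower in 37 of 38 members, with a median of -0.80 (camera adjusted p = 3.34e-07, and adjusted p = 0.530 with an estimated correlation); Rplp0 was at -2.21 ± 0.82, or -3.42 without cKO replicate 1, and Rpl4 at -1.90 ± 0.73, and DESeq2 called both (adjusted p = 0.0236 and 0.0275). In the libraries numbered 1 and 2 these 3 lists passed with medians of -0.94, 1.22 and -0.85. By camera with an estimated correlation each had an adjusted p = 0.816 there. That version has little power in so few libraries, so its failure there decides nothing. With the covariate the ribosomal protein list did not pass (median -0.21, camera adjusted p = 0.682). Without cKO replicate 2 it did not pass either (median -0.24), and the nuclear median was -0.73; without cKO replicate 1 the nuclear median was -2.72 and the ribosomal protein median -2.01. Among rows of high abundance, Lars2 took 0.752% and 11.7% of reads in cKO replicates 1 and 2, 5.14% in WT replicate 1 and from 0.355% to 0.880% in the other WT libraries.

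**Figure D3:**
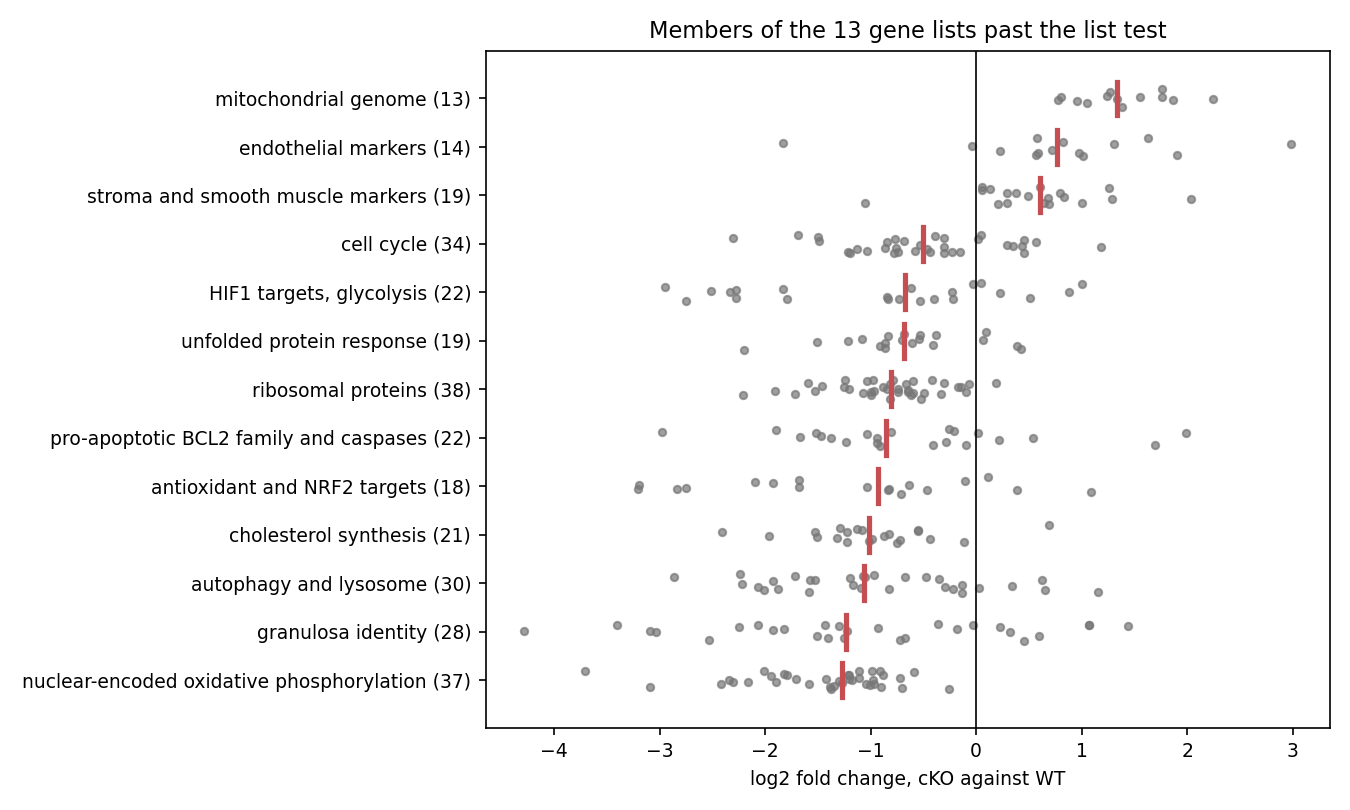
Log2 fold change (cKO against WT, horizontal axis) of each tested member (grey points) of the 13 gene lists that passed camera's test with the preset correlation; red lines are medians and the number tested stands in brackets. Mitochondrial genome genes lie to the right of 0 (13 of 13) and nuclear oxidative phosphorylation genes to the left (37 of 37).

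Several lists of metabolism, growth and stress were lower in cKO. Cholesterol synthesis genes were lower in 20 of 21 members (median -1.01, camera adjusted p = 0.000133, and adjusted p = 0.524 with an estimated correlation), with Msmo1 at -1.97 ± 0.65 (SE) and Srebf2, which encodes a sterol-sensing transcription factor, at -1.22 ± 0.44. Autophagy and lysosome genes were lower in 25 of 30 (median -1.06, camera adjusted p = 7.03e-05, and adjusted p = 0.524 with an estimated correlation), with Gabarapl2 at -2.07 ± 0.67 and Sqstm1, an autophagy receptor gene, at -1.87 ± 0.63. Antioxidant and NRF2 target genes were lower in 15 of 18 (median -0.93, camera adjusted p = 0.000238, and adjusted p = 0.524 with an estimated correlation); Prdx6 (peroxiredoxin 6), at -2.84 ± 0.65, passed when adjusted over the list alone (adjusted p = 0.011), and Prdx1 was at -2.75 ± 0.99. Cell cycle genes were lower in 25 of 34 (median -0.50, camera adjusted p = 0.036, and adjusted p = 0.664 with an estimated correlation), with the cyclin genes Ccnb2 at -2.30 ± 0.62 and Ccna2 at -1.49 ± 0.52. Genes of the unfolded protein response were lower in 15 of 19 (median -0.69, camera adjusted p = 0.011, and adjusted p = 0.562 with an estimated correlation), with Manf at -2.19 ± 0.72 and Sdf2l1 at -1.51 ± 0.63. With the number of detected genes as a covariate, none of these 5 lists passed. The tests of cholesterol synthesis (median -0.38, camera adjusted p = 0.914) and autophagy (-0.13, 0.946) then turned direction. Antioxidant genes (-0.30, 0.682), the cell cycle (-0.57, 0.243) and the unfolded protein response (-0.31, 0.682) did not. None of these 5 lists passed in the libraries numbered 1 and 2 either, with medians of -0.45 for cholesterol synthesis, -0.33 for autophagy, -0.48 for antioxidant genes, -0.23 for the cell cycle and -0.40 for the unfolded protein response. Without cKO replicate 2 the autophagy (-0.59), antioxidant (-1.02), cell cycle (-0.32) and unfolded protein response (-0.38) lists did not pass; the cell cycle call was also lost without WT replicate 2 (-0.42), 5 (-0.39) or 6 (-0.24), and that of the unfolded protein response without WT replicate 6 (-0.42). Without cKO replicate 1 the medians of the 5 lists were -1.65, -1.77, -2.41, -0.96 and -1.22, in the order above. There Manf was at -3.31 and Sdf2l1 at -3.06. Sdf2l1 was at -0.91 without cKO replicate 2. Of the genes named here, DESeq2 called Sqstm1 (adjusted p = 0.0444), Prdx6 (0.00167), Prdx1 (0.0264), Ccnb2 (0.0144) and Manf (0.0254).

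Heat shock, immediate early and interferon response genes did not pass the list test. Heat shock genes (14 tested) had a median of -0.45 (camera adjusted p = 0.176). Hspa1a, an inducible HSP70 gene, at -5.18 ± 1.28 (SE) and with 2 reads in cKO, passed when adjusted over the list alone (adjusted p = 0.017). Dnaja1 was at -1.41 ± 0.59, or -2.16 without cKO replicate 1. Hspa1a had 0 reads in cKO replicate 2, so its fitted -9.37 without cKO replicate 1 is not a measured size. The limit of 3 reads there is 4.61 CPM, against a mean of 26.6 CPM in WT. The heat shock median was -1.26 without cKO replicate 1 and 0.0150 without cKO replicate 2. Immediate early genes (16 tested) had a median of -0.29 and a mean of -0.07, while the list test gave the opposite direction (camera adjusted p = 0.616). Fosl2 was at -1.85 ± 0.83 (0.14 in the libraries numbered 1 and 2) and Junb at -2.46 ± 1.43 (4 reads in cKO). Interferon response genes (24 tested) had a median of 0.25 (camera adjusted p = 0.467). Ifit2 was at 3.36 ± 1.54, on 12 reads in cKO and 8 in WT, so its size is uncertain. Bst2 was at -1.16 ± 0.67, or -2.98 without cKO replicate 1 and -0.50 without cKO replicate 2. The interferon median was -0.25 and -0.40 without these, 0.00605 without WT replicate 1 and 0.39 without WT replicate 5.

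Markers of other cell types that a captured follicle could hold took small shares of the reads, and the mitochondrial genome took a larger one in cKO. Mitochondrial genome genes took 9.69% ± 1.15 of reads in cKO (SD, n = 2) and 2.77% ± 1.03 in WT (SD, n = 6), with no overlap (exact two-sided permutation test over 28 splits, p = 0.036, the smallest it can give; adjusted p = 0.286 over 8 shares). Theca markers took 0.0401% in cKO and 0.0727% in WT, stroma and smooth muscle markers 0.156% and 0.104%, endothelial markers 0.0512% and 0.0326%, and oocyte markers 0.0214% and 0.106%. Immune markers took 0.00729% and 0.00422%, red blood cell markers 0.0243% and 0.0194%, and surface epithelium markers 0.0129% and 0.00768%. The adjusted exact permutation p lay between 0.429 and 0.607 for these 7 shares. As lists, stroma and smooth muscle markers were higher in 18 of 19 members (median 0.61, camera adjusted p = 0.022, and adjusted p = 0.664 with an estimated correlation), with Pdgfra at 2.04 ± 0.90 and Dcn at 1.0 ± 0.70, which were 0.72 and -0.37 without cKO replicate 1. Stroma markers took 0.238% of reads in cKO replicate 1 but 0.0731% in cKO replicate 2, below the WT mean. Endothelial markers were higher in 12 of 14 (median 0.77, camera adjusted p = 0.00823, and adjusted p = 0.526 with an estimated correlation), with the transcription factor gene Sox17 at 2.99 ± 1.51 (4.92 without WT replicate 1) and Emcn at -1.83 ± 1.39 (-1.12 without WT replicate 5). Without cKO replicate 1 neither list passed, with medians of -0.59 for stroma and 0.0454 for endothelial markers, and the stroma call was also lost without WT replicate 3 (0.58) or 6 (0.38), while its median was 0.99 without cKO replicate 2. Neither passed in the libraries numbered 1 and 2 (medians 0.31 and 0.32). Both passed with the number of detected genes as a covariate, which does not overlap between the groups (medians 3.20 and 3.37, camera adjusted p = 9.75e-21 and 1.20e-12).

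The other cell type lists did not pass. Theca markers (13 tested) had a median of -0.88 (camera adjusted p = 0.583), with Mgarp at -3.37 ± 1.47 (SE), which turned to 1.76 in the libraries numbered 1 and 2. With the number of detected genes as a covariate, theca markers passed as higher (median 1.01, camera adjusted p = 0.000533). Interferon response (0.93), basal lamina (1.32) and oocyte markers (-9.66) also passed with it. That covariate does not overlap between the groups, so the fitted -9.66 is not a measured size. Immune markers (10 tested) had a median of 1.5 (camera adjusted p = 0.074), with the macrophage genes Csf1r at 2.87 ± 1.498 and C1qa at 2.59 ± 1.66, which were 1.55 and 1.53 without cKO replicate 1. C1qa rested on 18 reads in cKO and 19 in WT. Csf1r was at 4.93 without WT replicate 3. The immune median was 0.55 without cKO replicate 1, and 0.48, 0.86, 0.21, -0.0901 and 0.33 without WT replicates 2 to 6. Red blood cell markers (5 tested) had a median of -0.53 (camera adjusted p = 0.956), with Alas2 at -2.37 ± 1.55 and Hbb-bs at -0.97 ± 1.33, which were -1.15 and -4.35 without cKO replicate 1. Hbb-bs had 1.37 CPM in cKO replicate 2, below the limit of 3 reads in that library (4.61 CPM), so the size of -4.35 is uncertain. Hbb-bs was at -0.23 without cKO replicate 2. Alas2 had 0 reads in cKO replicate 1, so its fitted -7.87 without cKO replicate 2 is not a measured size. The limit of 3 reads there is 1.46 CPM, against a mean of 8.67 CPM in WT. Alas2 was at -1.41 without WT replicate 6 and Hbb-bs at 0.21 without WT replicate 4. Surface epithelium markers (5 tested) had a median of 1.13 (camera adjusted p = 0.583), with Krt8 at -1.87 ± 0.65 and Wt1, also a granulosa cell gene, at 1.88 ± 0.76. Oocyte markers (23 tested, 21 lower) had a median of -3.22, or -3.15 with the 2 genes that had no read in cKO set at their limit of 3 reads over the group (camera adjusted p = 0.186). In the libraries numbered 1 and 2 the oocyte list passed, with a median of -2.64 (camera adjusted p = 4.26e-16). By camera with an estimated correlation, which has little power in so few libraries, its adjusted p was 0.816. The oocyte list also passed without WT replicate 3 (-3.57), 4 (-3.53) or 5 (-3.45). The 2 genes with no read in cKO were Dppa3, at least 17.2-fold lower, and Nobox, at least 8.22-fold lower, limits that cover counting error only. WT replicate 6 set both, and without it they were 5.51-fold and 1.75-fold. Over the 13 lists that passed with the preset correlation, 0 passed with an estimated correlation and 0 by fry. Without cKO replicate 2 the number of lists passing was 6. Of the named genes, 25 moved over 1.5 times or turned when 1 library was left out, 23 of them with a cKO library. DESeq2 called 21 of the named genes and gave some of them no adjusted p. Of 62 given in the libraries numbered 1 and 2, 4 turned there and 26 fell by over 1.5 times. Beside the oocyte list, lists that did not pass over all 8 libraries but did when 1 was left out were other HIF1 targets (median -1.14) and heat shock genes (-1.26) without cKO replicate 1, the basal lamina list without cKO replicate 2 (0.67) or WT replicate 5 (0.51), and immune markers without WT replicate 3 (0.86).

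**Figure D4:**
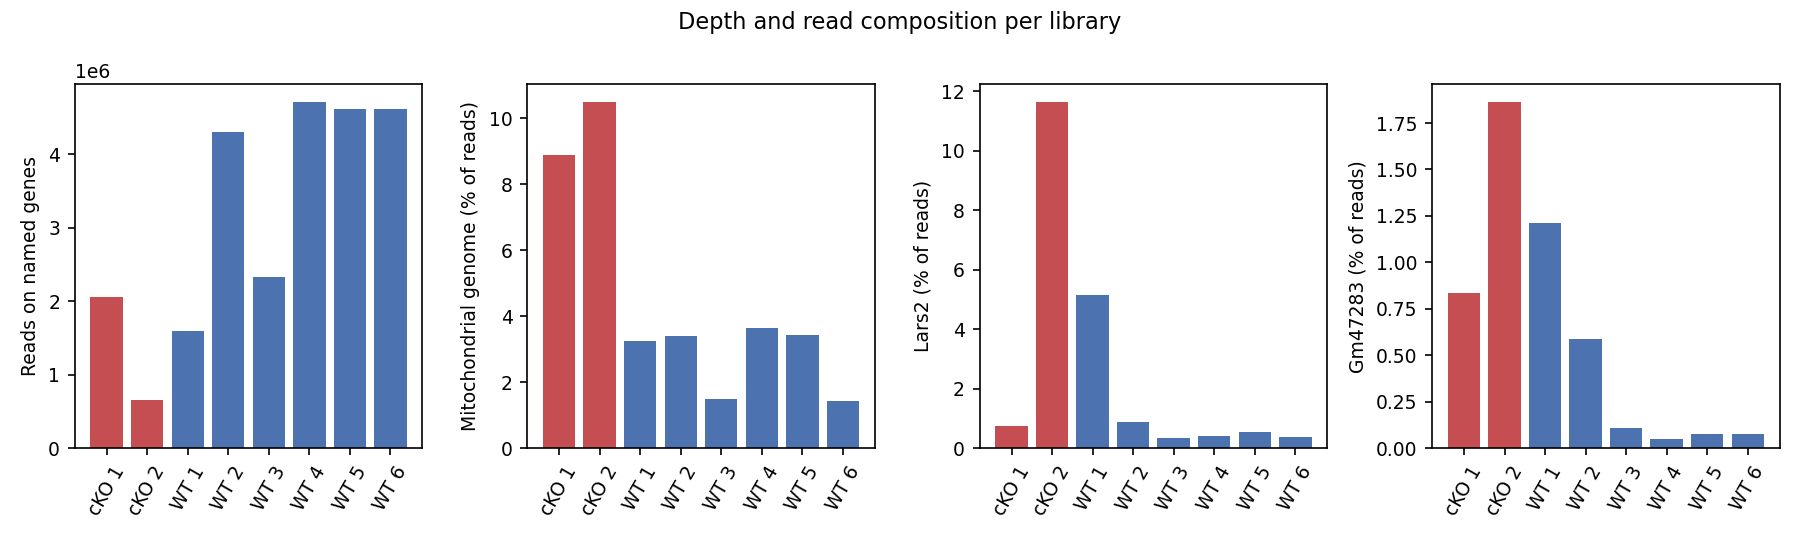
Number of reads on named genes and the percent of reads on the mitochondrial genome, Lars2 and Gm47283 (vertical axes) in each of the 8 libraries (bars, cKO red and WT blue). The mitochondrial genome took 8.87% and 10.5% in the cKO libraries and from 1.42% to 3.65% in the WT libraries.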

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

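In this part the tests of thinning, of the gap to matched genes per library, of the libraries numbered 1 and 2, of the ribosomal protein list and of other splits of the libraries were chosen after the results were seen, the libraries numbered 1 and 2 after Gm47283 and then granulosa genes, Amh and Inhba among them, had set them apart from WT replicates 3 to 6; detected genes as a covariate was planned, but how to read its result was set afterwards.

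Among 82 values tested over the 6 WT libraries, 10 had a library far from the others by Dixon's test. Chance gives about 1 in 20 where values are normally distributed. These were untransformed CPM and shares, and some marker genes also count in a share, so an excess over chance is not shown. WT replicate 6 held 0.401% of reads on oocyte markers, where the other WT libraries held from 0.00782% to 0.150%, with Dppa3 at 83.4 CPM and Nobox at 44.7 CPM. WT replicate 1 held 0.0749% of reads on endothelial markers, with Sox17 at 10.99 CPM, and it stood apart in Lars2, at 5.14%, and in Gm20594, at 2.85%. WT replicate 3 stood apart in Hspa1a, at 77.6 CPM, and in Csf1r, at 10.9 CPM. WT replicate 4 stood apart in Hbb-bs, at 104 CPM.

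The first pattern weighed is the higher mitochondrial genome and lower nuclear oxidative phosphorylation genes in cKO; the median of the nuclear list, -1.27, was at percentile 0 of 10000 random lists matched on length and expression (their median was -0.45), and at percentile 0.01 without cKO replicate 2 (-0.73, against lists matched in that fit). Those lists draw genes one by one, while the members correlate (0.777). Taken per library, the gap to matched genes overlapped between groups (exact p = 0.071 over 28 splits), so for the nuclear list a bias against short transcripts stays open. The ribosomal protein list, at percentile 12.3, was within its matched lists. The mitochondrial genome list, at 1.34, was at percentile 100 (median of its matched lists -0.54). Its gap per library was 1.03 and 2.26 in cKO and from -1.49 to 0.0540 in WT (exact p = 0.036, the smallest possible). These values argue against such a bias for the mitochondrial genome genes. After thinning to equal depth the nuclear median was -1.14. Random thinning keeps the expected share of each gene, so this value cannot decide on depth or on what made a library shallow. With the number of detected genes as a covariate the nuclear median was -0.38 and the mitochondrial genome median 2.05 (median SE of the members 1.08 and 1.24; camera adjusted p = 0.393 and 4.47e-10), but that number did not overlap between groups (at most 12847 in cKO, at least 13597 in WT), so library complexity and genotype cannot be told apart. The cKO genotype stays open: among the libraries numbered 1 and 2 the nuclear median was -0.94, a call with the preset correlation only. An estimated correlation leaves little power in so few libraries.

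The second pattern is the lower granulosa identity list. Among the libraries numbered 1 and 2 its median was -0.23 against -1.24 over all libraries, but those libraries were picked after members of this same list had been seen to differ there, so a smaller median was to be expected and decides nothing. A difference of those libraries from WT replicates 3 to 6, in follicle type or in preparation, and the cKO genotype cannot be told apart, as the labels give neither follicle type nor preparation. Other cells in the captured tissue stay open: stroma and endothelial lists were higher with the preset correlation, but not with an estimated one (adjusted p = 0.664 and 0.526), and their medians without cKO replicate 1 were -0.59 and 0.0454. Both lists passed as higher with detected genes as a covariate (medians 3.20 and 3.37), a number that does not overlap between the groups.

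The third is the count of 1855 genes at an unadjusted p under 0.05. Of the 28 splits of the libraries into 2 and 6, 2 gave as many, the real one included, so chance cannot be excluded. The highest of the other splits, 3380 genes, set cKO replicate 2 and WT replicate 1 against the rest. These were the shallowest libraries and those with the most Lars2. Both traits were looked up after this split was seen, and neither was tested as the cause of its count.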

How the results depend on the processing

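The comparisons restricted to the libraries numbered 1 and 2, the thinning and the removal of abundant rows were chosen after seeing the data. In the libraries numbered 1 and 2, camera with an estimated correlation has little power, as the samples are few. Hif1a, Bcl2l1, Bcl2l11 and Foxo1 were lower in cKO under every alternative run, Hif1a between -2.33 and -0.32 on the log2 scale (adjusted p from 0.062 to 1), and never passed the adjusted threshold. Of 69 named genes, 58 kept their direction in every alternative that gave them, from 15 alternatives for C1qa to 23 for Hif1a. Most were picked for a small p in the main fit, so a kept direction is no independent test. Genes called numbered 0 in edgeR and 478 with no filter, 253 with DESeq2, 5 with limma on log2(TPM + 1) (Cyyr1, Fcrls, Myh6, 3110040N11Rik and Sphk1), 1 after thinning (Myh6), and from 0 to 1 when 1 library was left out (Gm11718 without cKO replicate 1, Gm21541 without cKO replicate 2); the causes were not tested. Genes at an unadjusted p under 0.05 numbered 1855, and 3486 with no filter (25322 genes tested), 490 with detected genes as a covariate, 292 in the libraries numbered 1 and 2 (fewer samples), and from 865 to 3015 when 1 library was left out. Of these, 72.3% were lower in cKO, and 41.4% of 2486 with limma-voom. Lists passing numbered 13, and 18 with no filter, 0 with an estimated correlation, 0 by fry, 7 with the covariate, 4 in the libraries numbered 1 and 2 (0 there with an estimated correlation, also chosen after seeing the data), and from 6 to 14 when 1 library was left out. Shares without overlap between groups numbered 1, and 2 with summed TPM, 2 in the libraries numbered 1 and 2, and from 1 to 4 when 1 library was left out.

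With the replicate number as a block, 1 gene was called (Gm48128), 179 had an unadjusted p under 0.05 and 6 lists passed, with 1 residual degree of freedom. The labels do not say that the numbers pair libraries. The same-numbered correlations were -0.29 and -0.17 for the only 2 shared numbers. With 2 cKO libraries, each WT library correlates with both at equal size and opposite sign, so these values cannot test pairing. Under the block these turned direction: Lhcgr (0.98), Fosl2 (0.04997), Mgarp (1.67), Hbb-bs (0.66), and the lists of FOXO factors (median 0.22), luteinization (0.13), immediate early genes (-0.11), theca (0.0740), red blood cell (-0.0835) and surface epithelium markers (-0.99).

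A list is said to turn where the direction of its test did, and its median can keep its sign. With detected genes as a covariate, Cat (0.94), Dnaja1 (0.20), Fosl2 (0.0303), Vcan (-0.0559), Emcn (1.37), Csf1r (-2.04), Hbb-bs (1.68) and Lamc1 (0.19) turned, as did the lists of FOXO factors (-0.31), luteinization (0.48), cholesterol synthesis (-0.38), autophagy (-0.13), heat shock (0.20), immediate early genes (-1.02), cumulus expansion (-0.50), theca (1.01), red blood cell (-0.33) and surface epithelium markers (-0.51); theca markers then passed in the higher direction. In the libraries numbered 1 and 2, Lhcgr (0.72), Fosl2 (0.14), Mgarp (1.76) and Hbb-bs (0.25) turned, as did the lists of FOXO factors (0.12), luteinization (0.15), immediate early genes (-0.70), theca (0.11), red blood cell (0.25) and surface epithelium markers (-0.47), and the theca share (a difference of 0.00313 percentage points). The red blood cell list also turned with no filter (-0.18), with 10 reads in 6 libraries (0.45) and after thinning (0.21); with that stricter filter so did interferon response (-0.18) and theca markers (-0.0161). Oocyte markers turned with limma-voom (0.75), and Vcan with the effective length offset (-0.33). When 1 library was left out, the ranges of what turned were -4.35 to 0.21 for Hbb-bs, -0.37 to 1.58 for Dcn, and, as list medians, -1.73 to 0.52 for red blood cell, -0.59 to 0.99 for stroma, -4.33 to -1.49 for oocyte, -1.84 to -0.62 for theca and -3.34 to 1.48 for surface epithelium markers, -1.06 to -0.20 for FOXO factors, -1.26 to 0.0150 for heat shock and -0.43 to 0.27 for immediate early genes. The stroma share ranged from -0.0307 to 0.135 and the red blood cell share from -0.011 to 0.0208 percentage points. The cause of these turns was not tested. The depth of cKO replicate 2, 651426 reads, limits genes of low abundance most.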

Other observations

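Oocyte transcripts differed more between WT libraries than between the groups. Of 23 tested oocyte markers, 19 were highest in WT replicate 6. The share of reads on these markers was 0.401% there, 0.150% in WT replicate 2, 0.0576% in WT replicate 1 and from 0.00782% to 0.0118% in WT replicates 3 to 5, against 0.0275% and 0.0154% in cKO replicates 1 and 2.

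Of the abundant rows, Gm10925 and Gm29216, pseudogenes on chromosome 1, matched mt-Atp6 over 678 bases at 100% identity and mt-Co1 over 483 bases at 99.8%, and Gm20594 on chromosome 6 matched mt-Rnr2 over 435 bases at 88.5%. Estimated counts of mt-Atp6 and mt-Co1 are therefore shared with near-identical copies and uncertain. Gm47283, which the annotation places on chromosome Y, took 0.834% and 1.87% of reads in the cKO libraries, 1.21% and 0.589% in WT replicates 1 and 2, and from 0.0474% to 0.109% in WT replicates 3 to 6. The cells were cut from ovaries, so an origin of its reads on chromosome Y is unlikely. Where these reads came from was not tested. Across genes, the quartile with the shortest effective lengths had a median log2 fold change of -0.29 and the quartile with the longest 0.22.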
